A study of Mus musculus with 12 samples.

How the data were processed

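The data are bulk RNA sequencing of hearts from 12 mice, with 3 hearts in each of 4 groups. Per the labels, the animals were exposed in utero to filtered air or to diesel exhaust from embryonic day 0.5 to 17.5. At 12 weeks of age they had either a sham operation or transverse aortic constriction (TAC), in which a tie around the aorta, set with a 27 gauge needle, loads the left ventricle with pressure. Hearts were imaged by echocardiography at 11 weeks and taken at 15 weeks. The imaging values are not analysed here. Litter, sex and sequencing run are not given in the sources used here, although 4 samples shared each run. Each replicate has its own number in the labels and was taken as a separate heart, and the p-values of single genes measure the spread between these samples. Since the exposure was in utero, hearts of 1 group may come from the same litter. The tests of exposure treat hearts as independent, and with shared litters their p-values would be too small.

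Libraries of total RNA were made after ribosomal RNA depletion and sequenced on an Ion semiconductor instrument. Per the submitters' processing notes, the reads were trimmed with cutadapt 1.6, aligned to the mouse build mm10 with Subread 1.4.2 and counted per gene with featureCounts. The deposited values are raw counts per Entrez gene number for 27179 genes. The strand setting, the treatment of reads that map to several places and the annotation version are not given in the sources used here. Counts of overlapping antisense genes, of paralogs such as Acot1 and Acot2, and of microRNA genes inside a host gene, such as Mir208b within Myh7, can therefore hold reads of their neighbour or relative.

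Symbols were matched on the gene number in a RefSeq table of the assembly GRCm38.p6 for 25275 genes and in GENCODE M21 for 18 more. The 1886 genes without a symbol held 4.19% of all counts. Total counts per library ran from 5534685 to 13265816, and 100592512 counts were read in all. A count of 3 in a library corresponded to between 0.226 and 0.542 CPM, the count scaled to a common library size, which was taken as the floor per library and covers counting error only. Mitochondrially encoded RNA took 18.3% to 32.4% of the counts of a library and the titin gene Ttn 3.88% to 6.32%. No library was a copy of another.

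The main analysis used R 4.3.3 with edgeR 4.0.16. CPM were computed here from the deposited counts with TMM factors. Genes were kept by filterByExpr with a count minimum of 10, which left 13626. A quasi-likelihood model with a mean per group was fitted to all 12 libraries with 8 residual degrees of freedom, in its robust form. The tests were TAC against sham in each exposure, diesel exhaust against filtered air in each surgery, the exposure by surgery interaction, and the averages over exposure and over surgery. P-values were adjusted by Benjamini and Hochberg over the genes tested, within each of these comparisons, with a threshold of 0.05. Errors of log2 fold changes of genes are standard errors (SE), derived from the fold change and its quasi-likelihood F in the fit of all 12 libraries. Errors of CPM are standard deviations (SD). Each group has n = 3 libraries.

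Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The test was repeated with a correlation estimated for each list and with the rotation test fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. The 36 lists cover the hypertrophic fetal gene program, adult contractile and calcium handling genes, extracellular matrix and fibrosis, fatty acid uptake and oxidation, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, glycolysis, inflammatory cytokines and chemokines, interferon-stimulated genes, immediate early genes, the cell cycle, the circadian clock, cardiac ion channels and conduction, and microRNA genes of muscle and heart. Further lists hold oxidative stress response, unfolded protein and heat shock response, aryl hydrocarbon and xenobiotic response, DNA methylation and chromatin enzymes, imprinted genes, cytosolic ribosomal proteins and sex-linked genes. The cell type lists hold markers of macrophages and monocytes, neutrophils, T and B lymphocytes, endothelium, fibroblasts, smooth muscle and pericytes, erythrocytes, adipocytes, mesothelium and epicardium, ventricular cardiomyocytes, atrial cardiomyocytes, skeletal muscle, Schwann cells and neurons, lung, and thymus. The 32 lists with at least 5 measured members were tested.

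Genes are named by a rule. In each comparison it takes up to 10 rises and 10 falls with the greatest fold among genes past the threshold with a mean of at least 1 CPM and no overlap between the libraries of both groups. It adds the hallmark genes Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Postn and Col1a1, and the 4 members with the smallest p of each list past its threshold. Where fewer than 5 genes passed, it adds the 10 genes with the smallest p. Some genes that the rule takes are not reported here. The groups, tests, gene lists, named-gene rule and first set of alternatives were chosen before the data were examined.

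The alternatives were DESeq2 1.42.0 with its own size factors, RLE factors in edgeR, no filter, a minimum mean of 5 CPM, voom of limma with sample quality weights, removal of the 15 mitochondrial and 239 structural RNA genes, 1 surrogate variable from sva 3.50.0, a fit of the compared groups alone, and leaving out each library in turn. The procedure was tested on simulated counts for 13420 genes in which 100 genes were changed 2-fold and 100 genes 4-fold in the diesel TAC group. edgeR recovered 39% and 82% of these for TAC after diesel exhaust, 32% and 84% for diesel exhaust in TAC, and 13% and 64% for the interaction. Among unchanged genes it made 3, 6 and 8 calls in these comparisons and DESeq2 15, 17 and 13. For diesel exhaust in sham, where no gene was changed, edgeR made 0 calls and DESeq2 2. The 3 shifted lists were called and the 30 unshifted lists were not, by each of the 3 list tests. Genes were drawn independently of each other, so this cannot show how often a list is called wrongly when its genes move together. For the same reason the recovery of single genes may differ in the real libraries.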

Results

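Gene expression was measured in hearts of mice exposed before birth to filtered air or to diesel exhaust, after a sham operation or TAC in adult life. Each of the 4 groups had 3 libraries. In filtered air, the total count was 10403385, 7009097 and 6712369 for the sham hearts and 8579794, 7837190 and 8263299 for the TAC hearts. After diesel exhaust it was 8236531, 5534685 and 7328704 for sham and 13265816, 8320166 and 9101476 for TAC. Counts were found for 20355 genes, of which 13626 were tested. Log2 fold changes are given ± SE and levels in CPM ± SD, with n = 3 libraries per group throughout, and adjusted p-values are from edgeR unless another tool is named. Group means below the floor of 0.226 to 0.542 CPM per library rest on few or no counts, so a fold taken from them is not reliable.

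TAC against sham in filtered air asked how the heart responds to pressure load without the prenatal exposure. Matrix genes and genes of the fetal cardiac program rose. Cilp, a secreted matrix protein (gene number 214425, chromosome 9, 65265180 to 65280614 in GRCm38), rose 12-fold from 14.7 ± 2.1 to 176 ± 88 CPM (log2 3.59 ± 0.33, adjusted p = 1.47e-04). Nppb, which encodes B-type natriuretic peptide, rose 4.32-fold (log2 2.11 ± 0.27, adjusted p = 5.63e-04), and Postn, the matricellular protein periostin, rose 7.7-fold (log2 2.94 ± 0.33, adjusted p = 5.46e-04). Pla2g5, a secreted phospholipase, fell from 28.4 ± 5.9 to 8.47 ± 2.8 CPM (log2 -1.74 ± 0.27, adjusted p = 0.00153).

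**Figure D1:**
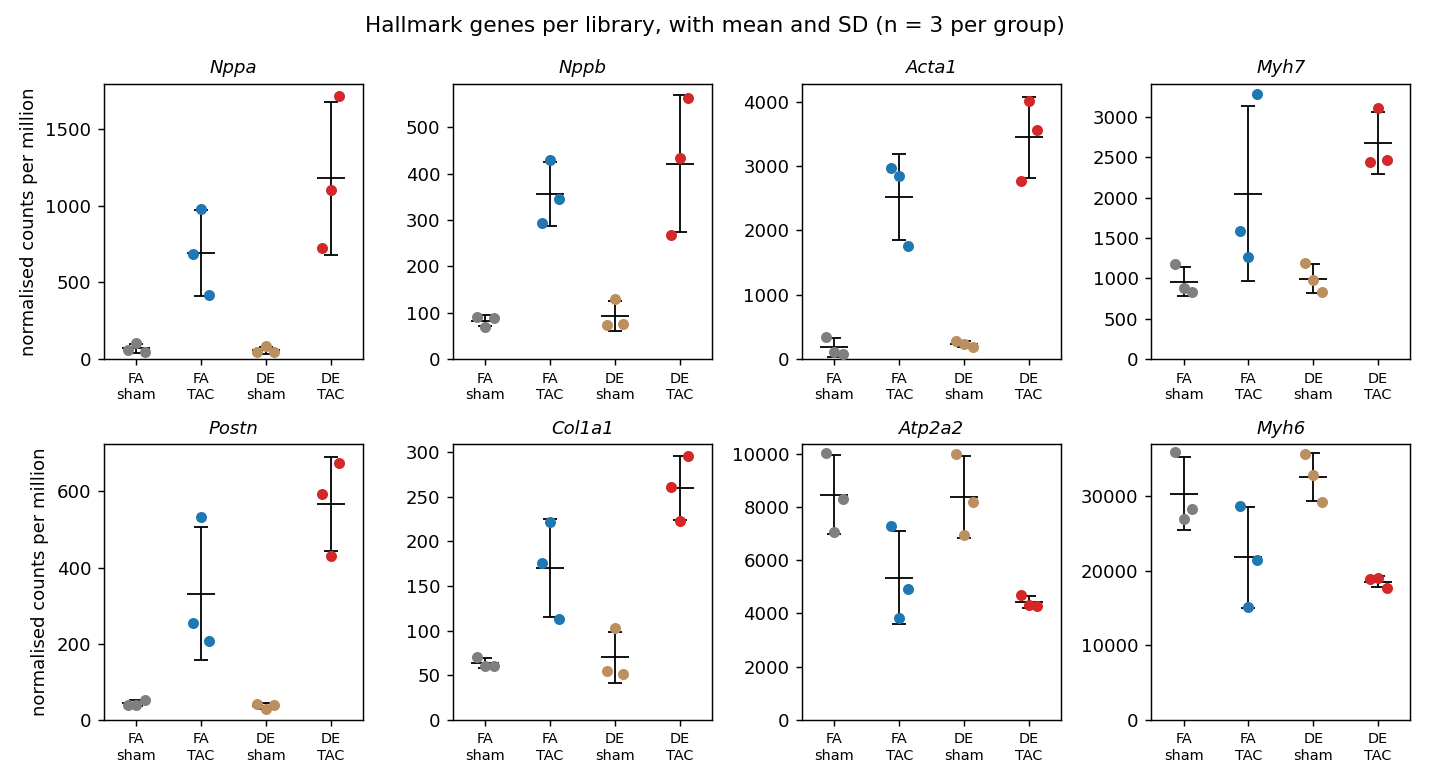
Normalised counts (CPM) of 8 hallmark genes on linear axes from 0, for filtered air (FA) and diesel exhaust (DE) with sham or TAC; points are libraries, and bars give the mean and SD of 3 libraries. Mean Nppa was 69.4 and 57.8 in the sham groups against 693 and 1179 in the TAC groups, and mean Postn 43.1 and 35.6 against 332 and 566.

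In filtered air, 113 genes passed the threshold, 83 higher and 30 lower after TAC, and 86 of them by more than 2-fold. The greatest rises besides Cilp included Thbs4 (a thrombospondin, log2 3.99 ± 0.55), Acta1 (skeletal alpha-actin, 3.80 ± 0.53), Col8a2 (a type VIII collagen chain, 3.67 ± 0.67), Nppa (atrial natriuretic peptide, 3.32 ± 0.50), Ltbp2 (a latent TGF-beta binding protein, 3.23 ± 0.42), Gpr65 (a proton-sensing receptor, 3.15 ± 0.75) and Tnc (tenascin C, 2.98 ± 0.49). Sphk1, a sphingosine kinase, was at 0.201 CPM in sham, below the floor, and 2.77 in TAC. The greatest falls were in Kcnv2 (a potassium channel subunit, log2 -2.17 ± 0.38), Ppl (periplakin, -1.91 ± 0.34), Pla2g5, Phkg1 (a phosphorylase kinase subunit, -1.74 ± 0.36), Cenpf (-1.67 ± 0.30), Med12l (-1.46 ± 0.32), Ciart (a repressor of the clock, -1.43 ± 0.29), Plxnb1 (a semaphorin receptor, -1.40 ± 0.22) and Kcnd2 (a channel of the transient outward current, -1.35 ± 0.25). Ccl11, the chemokine eotaxin, was at 3.06 ± 0.62 CPM in sham and 0.119 ± 0.21 in TAC, below the floor. The count was 56 without filtered-air sham replicate 1, 69 without replicate 2, 43 without replicate 3 and 39 without filtered-air TAC replicate 2. Of the 35 named genes past the threshold, 14 kept their call in each of the 12 fits without 1 library, among them Cilp, Ltbp2, Tnc, Nppb, Postn, Ppl, Pla2g5 and Plxnb1. Without TAC replicate 2 the adjusted p was 0.0759 for Acta1 and Nppa, 0.0575 for Col8a2, 0.0989 for Sphk1, 0.261 for Gpr65, 0.263 for Ccl11, 0.0542 for Kcnv2, 0.172 for Phkg1, 0.0602 for Cenpf, 0.145 for Med12l and Ciart and 0.075 for Kcnd2. Without sham replicate 1 it was 0.0821 for Thbs4, 0.108 for Nppa, 0.162 for Sphk1, 0.14 for Gpr65, 0.0742 for Ccl11, 0.081 for Phkg1, 0.0707 for Med12l and 0.091 for Ciart. Nppa also reached 0.0737 without sham replicate 3, and Kcnd2 0.0595 without sham replicate 2. Sphk1, Gpr65, Ccl11, Phkg1, Med12l and Ciart were also lost without 8, 8, 6, 3, 2 and 2 other libraries, each 1 at a time.

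Of the 49 measured genes of extracellular matrix and fibrosis, 25 rose and none fell in filtered air, with a mean log2 change of 1.69. Adjusted over the list alone, 47 rose and 1 fell. Col8a1 rose 5.48-fold (log2 2.46 ± 0.24, adjusted p = 2.01e-05), Fstl1, a follistatin-like glycoprotein, by 1.57 ± 0.19 (adjusted p = 1.92e-04) and Fn1, fibronectin, by 1.63 ± 0.21 (adjusted p = 3.29e-04). Of 18 fibroblast markers 4 rose (8 adjusted over the list alone), with a mean of 0.74 and adjusted p = 0.0857 with an estimated correlation. Mfap5 rose by 2.52 ± 0.38, Lum, lumican, by 1.21 ± 0.23 and Col1a1 by 1.42 ± 0.26. Col1a1 missed the threshold without sham replicate 1, 2 or 3 or TAC replicate 2 (adjusted p = 0.0558, 0.058, 0.0787 and 0.0759), Lum without sham replicate 2 or 3 or TAC replicate 2 (0.0513, 0.0758 and 0.0934) and Mfap5 without sham replicate 3 (0.0713). In the hypertrophic fetal gene program, 6 of 22 rose (10 adjusted over the list alone), among them Mybpc2 (1.84 ± 0.22), Xirp2 (1.68 ± 0.23) and the titin-binding stress protein Ankrd1 (1.87 ± 0.26). The mean of that list was 0.96, and its call and that of the matrix list held with an estimated correlation.

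Lists of fatty acid use, oxidative phosphorylation, mitochondrially encoded genes, ion channels, contraction and ventricular cardiomyocytes passed as lower after TAC in filtered air with a preset correlation. The 25 glycolysis genes did not pass as a list (mean -0.04, adjusted p = 0.242), and 1 of them rose. Of 33 genes of fatty acid uptake and oxidation, 1 fell (5 adjusted over the list alone), with a mean of -0.35 and adjusted p = 0.0857 with an estimated correlation. That gene was Slc27a1, a fatty acid transporter (log2 -0.87 ± 0.20, adjusted p = 0.0392), which missed the threshold without any 1 of 6 libraries, with 0.274 at most, without TAC replicate 2. None of 48 nuclear genes of oxidative phosphorylation passed (mean -0.24, adjusted p = 0.101 with an estimated correlation). None of 13 mitochondrially encoded genes passed either (mean -0.39, adjusted p = 0.368 with an estimated correlation). Of 28 ion channel and conduction genes 2 fell, Kcnv2 and Kcnd2 (adjusted over the list alone, 7 fell and 1 rose), with a mean of -0.35 and adjusted p = 0.195 with an estimated correlation. Kcnv2 reached adjusted p = 0.0542 and Kcnd2 0.075 without TAC replicate 2. Of 27 contractile and calcium handling genes 1 fell (2 adjusted over the list alone), with a mean of -0.19 and adjusted p = 0.46 with an estimated correlation. It was Hrc, the histidine-rich calcium binding protein (log2 -0.75 ± 0.18, adjusted p = 0.0451), which missed the threshold without any 1 of 9 libraries, with 0.266 at most, without TAC replicate 2. None of 15 ventricular cardiomyocyte markers passed (1 fell adjusted over the list alone, mean -0.29, adjusted p = 0.139 with an estimated correlation). The contractile list was lost without TAC replicate 2 (adjusted p = 0.162) and without sham replicate 1 (0.0537). In 19 circadian clock genes 1 fell, Ciart (4 adjusted over the list alone), and the call of the list (mean -0.26) held with an estimated correlation, while Ciart reached adjusted p = 0.145 without TAC replicate 2.

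Markers of macrophages and monocytes had a mean log2 change of 0.62 in filtered air, with 0 of 20 genes past the threshold by edgeR over all genes and 4 higher adjusted over the list alone (adjusted p = 0.302 with an estimated correlation). Of 26 inflammatory cytokine and chemokine genes, Tlr4, the lipopolysaccharide receptor, rose (log2 1.00 ± 0.22, adjusted p = 0.025) and Ccl11 fell. Adjusted over the list alone 3 rose and 1 fell, and the list had a mean of 0.38 with adjusted p = 0.356 with an estimated correlation. The 29 cell cycle genes had a mean of 0.62 (adjusted p = 0.0857 with an estimated correlation), the 29 interferon-stimulated genes 0.28 (adjusted p = 0.311 with an estimated correlation) and the 20 endothelial markers 0.18 (adjusted p = 0.318 with an estimated correlation). No gene of these last 3 lists passed over all genes, and 2 endothelial markers rose adjusted over the list alone. Without TAC replicate 2 the adjusted p was 0.207 for Tlr4, 0.263 for Ccl11, 0.293 for the inflammatory list, 0.162 for the interferon list and 0.204 for the endothelial list, and without sham replicate 1 it was 0.101, 0.0742, 0.227, 0.088 and 0.17. Tlr4, Ccl11 and the endothelial list were also lost without 3, 6 and 6 other libraries, each 1 at a time.

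TAC against sham after diesel exhaust asked the same question in exposed animals. The matrix response was broad, and genes of fatty acid use fell with it. Postn rose 15.9-fold from 35.6 ± 7.2 to 566 ± 120 CPM (log2 3.99 ± 0.34, adjusted p = 2.18e-05), Nppa rose 20.4-fold (log2 4.35 ± 0.52, adjusted p = 0.00239) and Nppb 4.54-fold (log2 2.18 ± 0.27, adjusted p = 1.70e-04). Acot1, a cytosolic acyl-CoA thioesterase (gene number 26897, chromosome 12, 84009502 to 84017670), fell from 9.69 ± 2.6 to 1.61 ± 0.34 CPM (log2 -2.60 ± 0.40, adjusted p = 4.23e-04).

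After diesel exhaust 442 genes passed the threshold, 239 higher and 203 lower, and 262 of them by more than 2-fold. The greatest rises included Dio2 (the deiodinase that activates thyroid hormone, log2 4.73 ± 0.77), Ltbp2 (4.44 ± 0.43), Nppa, Thbs4 (4.31 ± 0.54) and Cilp (4.22 ± 0.33). Nox4, an NADPH oxidase, was at 0.0983 CPM in sham and 7.46 in TAC, Itih2 at 0.197 and 5.51, and Cthrc1, a secreted collagen regulator, at 0.0962 and 2.32. These sham means lay below the floor. Serpinb1c was listed at 0 in all 3 sham libraries and at 2.29 ± 1.2 CPM in TAC. The greatest falls were in Kcnv2 (log2 -2.67 ± 0.38), Acot1, Pla2g5 (-2.16 ± 0.27), Pfkfb1 (a regulator of glycolysis, -2.13 ± 0.43), Adra1b (an alpha-1 adrenergic receptor, -1.98 ± 0.28), Mrgprh (-1.94 ± 0.48), Lingo3 (-1.92 ± 0.40), Slc22a3 (an organic cation transporter, -1.91 ± 0.39) and Cenpf (-1.90 ± 0.30), while the kinase gene Sbk2 was at 2.5 CPM in sham and 0.34 in TAC. The count was 223 without diesel sham replicate 1, 264 without replicate 3, and 265, 209 and 188 without diesel TAC replicates 1, 2 and 3. Of the 58 named genes past the threshold, 34 kept their call in each of the 12 fits without 1 library. The adjusted p was 0.0571 for Pfkfb1 without TAC replicate 3 and 0.0537 for Slc22a3 without TAC replicate 2. For Lingo3 it was 0.052 and 0.0566 without sham replicate 1 and TAC replicate 2. Cthrc1 missed the threshold without any 1 of 4 libraries, Mrgprh without any 1 of 5 and Sbk2 without any 1 of 10, with highest values of 0.138 without sham replicate 1, 0.138 without sham replicate 3 and 0.216 without TAC replicate 3. By voom Dio2 had adjusted p = 0.107 and Nox4 0.0669.

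Of the 49 matrix genes, 43 rose after diesel exhaust (47 adjusted over the list alone), with a mean log2 change of 2.06. Col8a1 rose 7.89-fold (2.98 ± 0.24, adjusted p = 8.75e-07), Fstl1 4.12-fold (2.04 ± 0.20, adjusted p = 4.04e-06) and Bgn, biglycan, 3.97-fold (1.99 ± 0.21, adjusted p = 1.35e-05). Of 18 fibroblast markers 9 rose (12 adjusted over the list alone, mean 1.07), among them Mfap5 (3.21 ± 0.40), Lum (1.70 ± 0.23), Col1a1 (1.90 ± 0.26) and Dcn, decorin (0.97 ± 0.21). In the fetal gene program 9 of 22 rose, and 12 rose and 2 fell adjusted over the list alone, with a mean of 1.02. Acta1 (3.88 ± 0.53), Xirp2 (a 4-fold rise), Ankrd1 (2.30 ± 0.26), Mybpc2 (1.28 ± 0.22) and the beta myosin heavy chain gene Myh7 (1.43 ± 0.28, adjusted p = 0.00798) were among them. Myh7 stood at 1.09 ± 0.28 (adjusted p = 0.0846) in filtered air, and its interaction estimate was 0.33 ± 0.39, below its threshold. In the cell cycle list 2 of 29 genes rose over all genes and over the list alone, Top2a (2.13 ± 0.39) and Mki67 (1.31 ± 0.27), with a mean of 0.81, although the kinetochore gene Cenpf fell. The calls of these 4 lists held with an estimated correlation. Myh7 missed the threshold without sham replicate 3 (adjusted p = 0.0508), and Dcn without sham replicate 3 (0.058) or TAC replicate 1 (0.0584).

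Of 33 fatty acid genes 8 fell after diesel exhaust and none rose (24 fell adjusted over the list alone), with a mean log2 change of -0.68. Besides Acot1, these included Slc27a1 (-1.42 ± 0.20, adjusted p = 2.45e-04), the mitochondrial thioesterase Acot2 (-1.28 ± 0.19, adjusted p = 4.23e-04) and the electron transfer flavoprotein subunit Etfb (-0.99 ± 0.20, adjusted p = 0.00769). Of 48 nuclear genes of oxidative phosphorylation 2 fell (13 adjusted over the list alone, mean -0.37), Cox7a1 (-1.10 ± 0.26, adjusted p = 0.0262) and Sdhc (-0.95 ± 0.24, adjusted p = 0.0292). Both of these list calls held with an estimated correlation. Of 25 glycolysis genes 4 fell and 1 rose (7 and 1 adjusted over the list alone), with a mean of -0.28 and adjusted p = 0.451 with an estimated correlation. The glucose transporter Slc2a4 (-0.84 ± 0.18) and the muscle phosphofructokinase Pfkm (-0.68 ± 0.17) fell with Pfkfb1, and the platelet isoform Pfkp rose (0.89 ± 0.19). Etfb missed the threshold without TAC replicate 2 (adjusted p = 0.0507) or 3 (0.0714), and Pfkp without sham replicate 3 (0.0619) or TAC replicate 3 (0.0824). Slc2a4 missed it without sham replicate 2 (0.0531) or TAC replicate 2 (0.0507) or 3 (0.079), and Pfkfb1 without TAC replicate 3 (0.0571). Cox7a1, Sdhc and Pfkm missed it without any 1 of 4, 4 and 6 libraries, with 0.135, 0.163 and 0.102 without TAC replicate 3. The glycolysis list was lost without sham replicate 2 (0.064) or TAC replicate 1 (0.0645).

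Of 28 ion channel and conduction genes 7 fell after diesel exhaust (9 adjusted over the list alone), with a mean of -0.50 and adjusted p = 0.118 with an estimated correlation. They included Kcnv2, Kcnd2 (-1.28 ± 0.24), the sodium channel subunit Scn4b (-1.14 ± 0.23) and Kcnh2 (-1.07 ± 0.24). Of 27 contractile and calcium handling genes 4 fell (8 adjusted over the list alone), with a mean of -0.26 and adjusted p = 0.372 with an estimated correlation. These were Hrc (-0.96 ± 0.18), Tcap, telethonin (-0.92 ± 0.19), cardiac troponin I, Tnni3 (-0.90 ± 0.24), and the calcium pump gene Atp2a2 (-0.92 ± 0.23, adjusted p = 0.0297), whose interaction estimate of -0.26 ± 0.33 did not pass. Of 15 ventricular cardiomyocyte markers 2 fell (5 adjusted over the list alone), Tnni3 and Corin, the protease that processes natriuretic peptides (-0.90 ± 0.18), with a mean of -0.46 and adjusted p = 0.0562 with an estimated correlation. Without TAC replicate 3 the adjusted p was 0.0668 for Scn4b, 0.079 for Tcap, 0.206 for Tnni3, 0.137 for Atp2a2 and 0.106 for Kcnh2. Tnni3, Atp2a2 and Kcnh2 also missed the threshold without 5, 4 and 3 other libraries, each 1 at a time, and Atp2a2 had its highest value, 0.144, without sham replicate 1.

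Of 29 interferon-stimulated genes 2 rose after diesel exhaust (3 adjusted over the list alone), Ifi27l2a (1.25 ± 0.30) and Rsad2 (1.02 ± 0.27), with a mean of 0.42 and adjusted p = 0.148 with an estimated correlation. Of 26 inflammatory genes Tlr4 (0.85 ± 0.22) and Ccl8 (0.0426 CPM in sham, below the floor, and 1.38 in TAC) rose. The list had a mean of 0.49 and adjusted p = 0.355 with an estimated correlation. Adjusted over the list alone 4 rose and 1 fell. The macrophage list had a mean of 0.50 with Mrc1, the mannose receptor, past the threshold (0.68 ± 0.18, 4 genes adjusted over the list alone, adjusted p = 0.355 with an estimated correlation). The endothelial list had a mean of 0.24 with Cd34 past the threshold over all genes and over the list alone (0.94 ± 0.17, adjusted p = 0.303 with an estimated correlation). Mesothelial and epicardial markers had a mean of 0.86 (11 genes, adjusted p = 0.376 with an estimated correlation) and microRNA genes of muscle and heart -0.97 (12 genes, adjusted p = 0.509 with an estimated correlation), with no gene past the threshold over all genes, although 1 microRNA gene fell adjusted over its list alone. Ifi27l2a, Rsad2, Tlr4, Ccl8 and Mrc1 each missed the threshold without any 1 of 5, 7, 4, 10 and 8 libraries. Their highest adjusted p was 0.109 and 0.183 without TAC replicate 1, 0.148 without TAC replicate 3, 0.174 without sham replicate 3 and 0.163 without TAC replicate 3. The endothelial, mesothelial, inflammatory and microRNA lists were lost without any 1 of 3, 3, 4 and 6 libraries. Their highest adjusted p was 0.139 for both of the first without TAC replicate 1, 0.0888 without sham replicate 1 and 0.392 without sham replicate 2. The circadian clock and mitochondrially encoded lists, which passed in filtered air, did not pass after diesel exhaust. Neither list passed the interaction test, so no difference between exposures was shown for them.

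**Figure D2:**
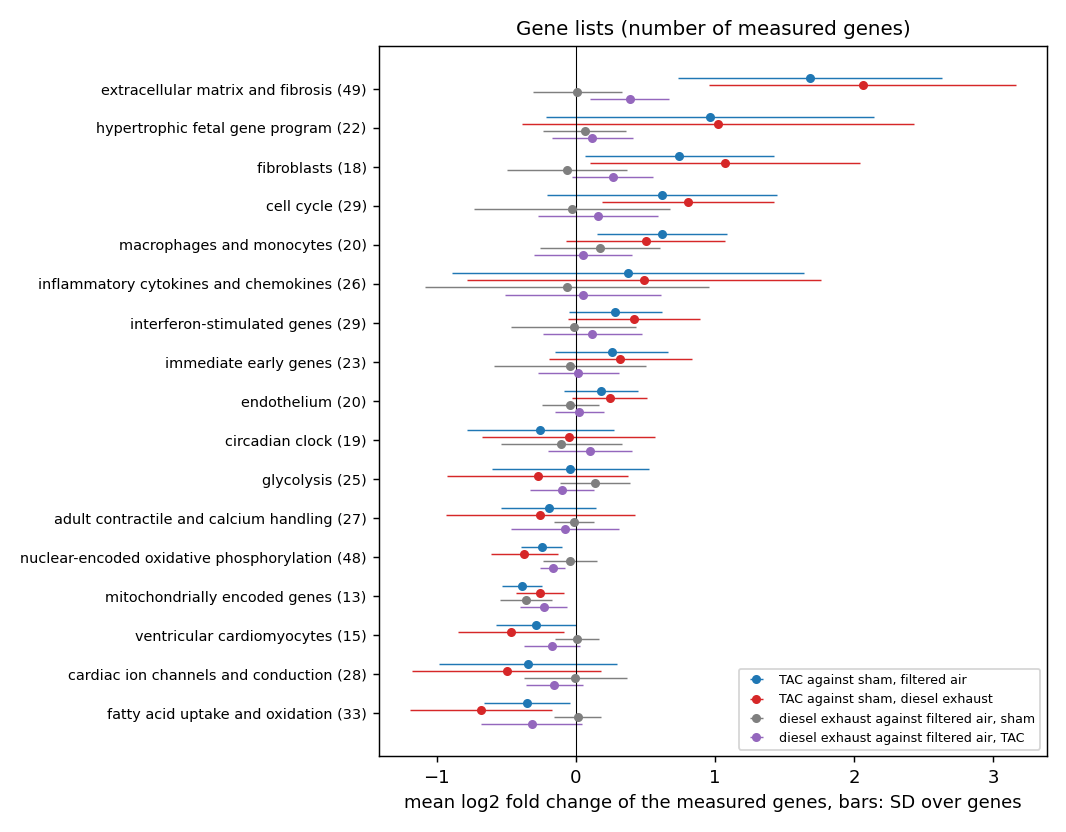
Mean log2 fold change of the measured genes of the 17 lists past their threshold for TAC averaged over exposure, with bars for the SD over genes, in TAC against sham for each exposure and diesel exhaust against filtered air for each surgery. The matrix list lay at 1.69 and 2.06 for TAC, and the fatty acid list at -0.35 and -0.68.

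Both TAC responses were set side by side to see how alike they were. They shared 95 genes past the threshold, 69 that rose in both and 26 that fell in both, and no gene passed in opposite directions. Independent sets of these sizes would share 1.46 and 0.447 genes. All 113 genes called in filtered air had the same sign after diesel exhaust, and 437 of the 442 called after diesel exhaust had the same sign in filtered air. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.524 and Spearman's rho 0.478 over 13626 genes, and 0.736 and 0.610 over the 7630 genes with a mean of at least 10 CPM. Of 1091 genes called in the average of both exposures, 798 (73.1%) had the larger change after diesel exhaust, with a median of 0.83 against 0.66 on the log2 scale. By edgeR with the expression filter no single gene passed the test of the difference, the interaction.

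**Figure D3:**
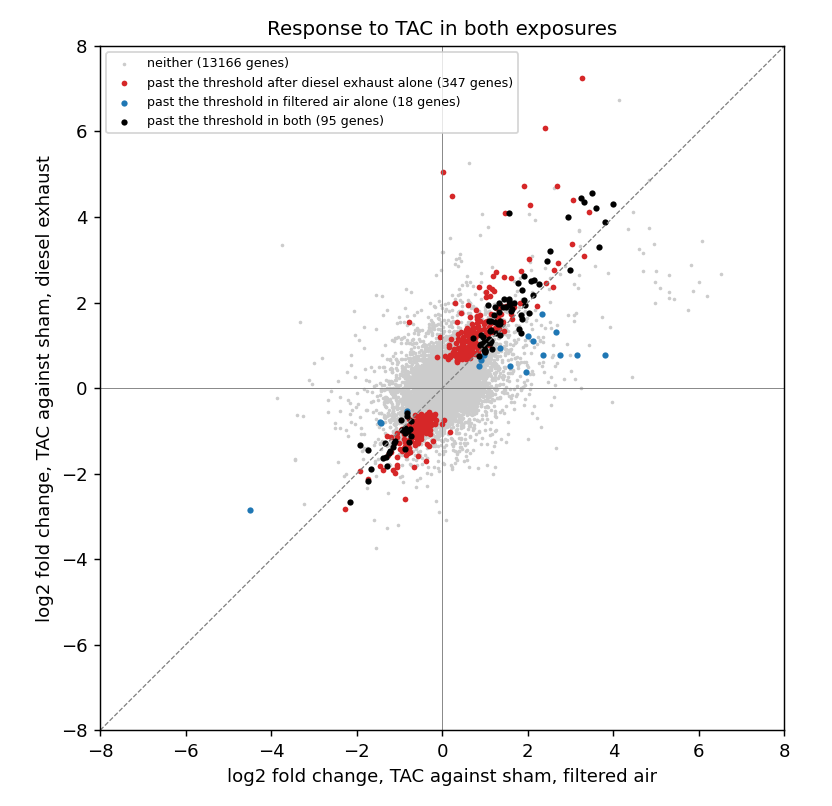
Log2 fold change of TAC against sham in filtered air (horizontal) and after diesel exhaust (vertical), 1 point per gene, coloured by where it passed the threshold; the dashed line marks equal change. The 95 genes past the threshold in both lie in the quadrants of equal sign, with 18 past it in filtered air alone and 347 after diesel exhaust alone.

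Averaged over exposure, TAC changed 1091 genes, 558 higher and 533 lower, 351 of them by more than 2-fold. Of the 75 named genes past the threshold, 60 kept their call in each fit without 1 library. Cilp rose 14.9-fold (log2 3.90 ± 0.23), Col12a1 13.7-fold (3.77 ± 0.56), Postn 11.1-fold (3.47 ± 0.24), Myh7 2.39-fold (1.26 ± 0.20) and Col8a1 6.58-fold (2.72 ± 0.17, adjusted p = 6.62e-09). Mgat5b, a glycosyltransferase gene, was at 0.0353 and 0.298 CPM in the sham groups, below the floor, and 1.5 and 2.25 in the TAC groups. Atp2a2 fell (-0.79 ± 0.16, adjusted p = 0.00388), as did the adult myosin heavy chain gene Myh6 (-0.65 ± 0.16, adjusted p = 0.0169), although Myh6 reached adjusted p = 0.0563 without filtered-air sham replicate 1. Lvrn, an aminopeptidase gene, fell by 2.34 on the log2 scale and reached adjusted p = 0.0532 without diesel TAC replicate 3. The dopamine beta-hydroxylase gene Dbh (-2.05 ± 0.51) reached 0.0725 and 0.0744 without replicate 1 of diesel sham and of filtered-air sham. Without filtered-air TAC replicate 2 the count was 631.

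By list, the averaged TAC response raised 45 of 49 matrix genes (48 up and 1 down adjusted over the list alone), 11 of 18 fibroblast markers (12), and 6 of 29 cell cycle genes (13), with mean log2 changes of 1.87, 0.91 and 0.71. In the fetal program 12 of 22 rose and 1 fell, also adjusted over the list alone (mean 0.99). It lowered 19 of 33 fatty acid genes (26), among them the isomerase Eci1 (-0.74 ± 0.13), and 12 of 48 genes of oxidative phosphorylation (20), among them the ATP synthase subunit Atp5d (-0.49 ± 0.12), with means of -0.52 and -0.31. These 6 calls held with an estimated correlation. Of 28 ion channel genes 10 fell and 1 rose (14 and 1 adjusted over the list alone), with a mean of -0.42 and adjusted p = 0.102 with an estimated correlation. Of 19 clock genes 5 fell (7), among them the output factor Dbp (-0.68 ± 0.12), with a mean of -0.15 and adjusted p = 0.0859 with an estimated correlation. Of 27 contractile genes 8 fell (9), with a mean of -0.22 and adjusted p = 0.368 with an estimated correlation, and of 15 ventricular cardiomyocyte markers 5 fell (8 fell and 1 rose), with a mean of -0.38 and adjusted p = 0.0569 with an estimated correlation. Of 20 macrophage markers 5 rose (6), among them Mpeg1 (1.09 ± 0.22), Cx3cr1 (1.98 ± 0.43) and the growth factor receptor Csf1r (0.58 ± 0.14), with a mean of 0.56 and adjusted p = 0.245 with an estimated correlation. Inflammatory genes (4 rose and 1 fell, 5 and 1 adjusted over the list alone, mean 0.43) had adjusted p = 0.248 with an estimated correlation. Interferon-stimulated genes (4 rose, 6 over the list alone, mean 0.35) had adjusted p = 0.135 with an estimated correlation, and endothelial markers (2 rose, 3 over the list alone, mean 0.21) had adjusted p = 0.219 with an estimated correlation. Glycolysis genes (1 rose and 5 fell, 3 and 8 over the list alone, mean -0.16) had adjusted p = 0.514 with an estimated correlation and were lost without filtered-air sham replicate 1 (0.091), diesel sham replicate 2 (0.0847), filtered-air TAC replicate 2 (0.0869) or diesel TAC replicate 1 (0.0655). Immediate early genes (1 of 23 rose, 0 over the list alone, mean 0.29) had adjusted p = 0.514 with an estimated correlation and were lost without diesel sham replicate 1 (0.0644) or 3 (0.0716) or filtered-air TAC replicate 1 (0.0728). Mitochondrially encoded genes (0 of 13 by edgeR, mean -0.32) had adjusted p = 0.459 with an estimated correlation and were lost without diesel sham replicate 3 (0.0554).

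Diesel exhaust against filtered air in sham hearts asked whether the prenatal exposure left a change in the unloaded adult heart. No gene passed the threshold. Among the hallmark genes, log2 differences were -0.27 ± 0.46 for Nppa, 0.17 ± 0.26 for Nppb, 0.05 ± 0.28 for Myh7 and 0.38 ± 0.48 for Acta1. They were -0.02 ± 0.23 for Atp2a2, -0.27 ± 0.31 for Postn and 0.13 ± 0.26 for Col1a1. The errors of Nppa and Acta1 leave room for larger differences. Among the genes with the smallest p were Bbip1, a subunit of the ciliary BBSome (-1.10 ± 0.27), the synaptic adhesion gene Nrxn2 (2.31 ± 0.61), Cadm1 (-2.30 ± 0.61), Echdc3 (0.88 ± 0.24), Nt5dc2 (1.05 ± 0.28), Pcdh1 (-0.90 ± 0.24), Celsr3 (1.48 ± 0.39), Pamr1 (-1.60 ± 0.43) and Cntfr, at 0.155 CPM in filtered air and 2.02 after diesel exhaust. The smallest adjusted p was 0.996. By edgeR 0 genes passed against 503 at an unadjusted p under 0.05, where 681.3 are expected with no difference, and DESeq2 and voom gave 0 against 543 and 379. With a covariate for a split of the libraries described in the closing section, edgeR called 1 gene, which has no symbol. The 13 mitochondrially encoded genes were all lower, with a mean of -0.36, and passed as a list, but with adjusted p = 0.949 with an estimated correlation. That call was lost without diesel sham replicate 2 (adjusted p = 0.199), the library with the lowest mitochondrial share, 18.3% of counts, and without filtered-air sham replicate 3 (0.121).

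Diesel exhaust against filtered air in TAC hearts asked whether the exposure altered the loaded heart. No gene passed the threshold by edgeR. Ptprf, a receptor tyrosine phosphatase, had the smallest p, at 4.41 ± 0.75 CPM after filtered air and 13.1 ± 2.6 after diesel exhaust (log2 1.57 ± 0.30, adjusted p = 0.523), and it was the 1 gene that DESeq2 called (log2 1.58, adjusted p = 0.00503). The next were the desaturase Scd1 (0.88 ± 0.24), Acot1 (-1.39 ± 0.40), the complement gene C7 (0.82 ± 0.24), Acot2 (-0.64 ± 0.19), Wfdc1 (-1.02 ± 0.31), Yipf7 (-0.58 ± 0.18), Arhgap42 (0.90 ± 0.29) and Cadm4 (-0.94 ± 0.31), with Trmt9b at 2.01 CPM in filtered air and 0.275 after diesel exhaust. Nppa differed by 0.77 ± 0.45, Nppb by 0.24 ± 0.26, Postn by 0.77 ± 0.30 and Col1a1 by 0.61 ± 0.25. By edgeR 0 genes passed against 255 at an unadjusted p under 0.05, by DESeq2 1 against 272 and by voom 0 against 708. With no difference 681.3 are expected. With no filter edgeR called Serpina1c, an alpha-1 antitrypsin gene with 139 counts in 5 libraries.

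In the same comparison 46 of 49 matrix genes had a positive difference (mean 0.39), with 0 past the threshold by edgeR and adjusted p = 0.479 with an estimated correlation. Ltbp2 (1.08 ± 0.35) and Bgn (0.58 ± 0.21) had the smallest p. Of 33 fatty acid genes 0 passed over all genes and 2 fell adjusted over the list alone (mean -0.32, adjusted p = 0.278 with an estimated correlation), with the mitochondrial trifunctional subunit Hadhb at -0.43 ± 0.16 and the kinase Pdk4 at -1.07 ± 0.41. Oxidative phosphorylation genes had a mean of -0.16 (adjusted p = 0.45 with an estimated correlation) and contractile genes -0.08 (adjusted p = 0.771 with an estimated correlation). Fibroblast markers had a mean of 0.26 (adjusted p = 0.485 with an estimated correlation) and mesothelial markers 0.79 (adjusted p = 0.485 with an estimated correlation), with Msln, mesothelin, at 1.09 and 3.78 CPM. No gene of these last 4 lists passed over all genes or over the list alone. Without filtered-air TAC replicate 1 the adjusted p was 0.836 for the contractile list and 0.118 for fibroblasts. Without filtered-air TAC replicate 3 it was 0.0803 for the contractile and mesothelial lists and 0.0984 for fibroblasts, and 0.157 for mesothelium without diesel TAC replicate 1 and for the contractile list without diesel TAC replicate 3.

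The interaction asked whether the TAC response differed between exposures. No gene passed the threshold by edgeR, with a smallest adjusted p of 0.336. That gene was Ptprf (gene number 19268, chromosome 4, 118208213 to 118291405), which stood at 7.56 ± 0.42 CPM in sham and 4.41 ± 0.75 in TAC after filtered air, and at 4.49 ± 1.2 and 13.1 ± 2.6 after diesel exhaust (log2 2.33 ± 0.44). DESeq2 called it (log2 2.34, adjusted p = 0.00283). Pamr1, a peptidase-domain gene linked to muscle regeneration, went from 2.97 to 8.68 CPM in filtered air and from 0.971 to 16.7 after diesel exhaust (log2 2.54 ± 0.54, adjusted p = 0.739). The next were the kinase Pim3 (-1 ± 0.25), Msln (3.74 ± 0.99), the potassium channel Kcna2 (-3.19 ± 0.84), Echdc3 (-1.22 ± 0.33), Enho (-1.97 ± 0.55), Cadm1 (2.95 ± 0.84), Ttyh2 (1.62 ± 0.47) and Msantd4 (-0.85 ± 0.25). Postn had 1.05 ± 0.43, Nppa 1.03 ± 0.65, Col1a1 0.48 ± 0.36 and Acot1 -1.74 ± 0.54. By edgeR 0 genes passed against 327 at an unadjusted p under 0.05, by DESeq2 1 against 384 and by voom 0 against 398. With no difference 681.3 are expected, so these counts are no surplus. They lie below that number, so the p-values may run too large, and the cause was not tested. With no filter edgeR called Capn11, a calpain gene with 66 counts in 5 libraries. Of the 460 genes called in either exposure, 57 had an interaction p under 0.05 before adjustment, against 327 of all 13626 genes. The 460 genes were picked on libraries that also enter the interaction, which favours a small p. Their count is therefore no independent evidence of a difference. In simulated counts the test recovered 64% of 4-fold and 13% of 2-fold differences. The simulated libraries held no departure shared between libraries, as described in the closing section for these data, so recovery here may differ.

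**Figure D4:**
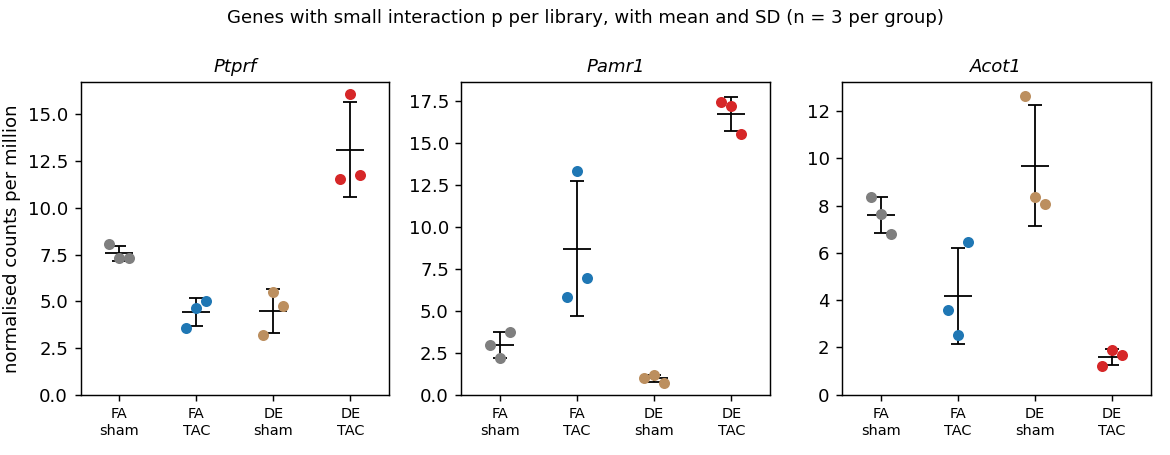
Normalised counts (CPM) of Ptprf, Pamr1 and Acot1 on linear axes from 0 in the 4 groups (FA, filtered air; DE, diesel exhaust); points are libraries, and bars give the mean and SD of 3 libraries. Mean Ptprf was 13.1 in the diesel TAC group and between 4.41 and 7.56 in the others, while mean Acot1 was 1.61 there and between 4.18 and 9.69 in the others.

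Averaged over surgery, diesel exhaust against filtered air gave 0 genes by edgeR against 452 at an unadjusted p under 0.05, with 0 by DESeq2 and voom against 502 and 657. Here too 681.3 are expected with no difference. Plcg2, a phospholipase C gene of immune cells, had the smallest p, with 0.76 ± 0.18 (adjusted p = 0.999). It stood at 9.49 and 16.6 CPM in the sham and TAC groups of filtered air and at 17.2 and 26.7 after diesel exhaust. The next were the splicing factor Cdc5l (-0.50 ± 0.14), Bhlhb9 (-0.83 ± 0.24), Zfp607a (-1.05 ± 0.31), the complement genes C7 (0.59 ± 0.17) and C4b (0.83 ± 0.23), Yipf7 (-0.43 ± 0.13), Map6 (0.82 ± 0.25) and Ilf2 (-0.51 ± 0.15), with Vcpkmt at 0.201 and 0.855 CPM against 1.48 and 1.86. The lists of matrix (mean 0.20, adjusted p = 0.841 with an estimated correlation), fatty acid use (-0.15, adjusted p = 0.61 with an estimated correlation), oxidative phosphorylation (-0.10, adjusted p = 0.61 with an estimated correlation) and mitochondrially encoded genes (-0.30, adjusted p = 0.61 with an estimated correlation) passed with the preset correlation, with no gene past the threshold over all genes or adjusted over its list alone. The matrix list was lost without filtered-air TAC replicate 3 (adjusted p = 0.13) and oxidative phosphorylation without diesel TAC replicate 3 (0.0577).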

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

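The tests of list counts over other groupings and of deeper libraries were set before their results were seen. The tests of gene counts over other groupings, of the size of the difference between responses, of cell shares and of Ptprf and Pamr1, and the limit to groupings with 1 first-listed library in each group, were chosen only after the result was seen.

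6 lists differed between exposures in their response to TAC by the interaction test with a preset correlation. The mean log2 difference was 0.38 for extracellular matrix and fibrosis (adjusted p = 3.6e-06), with Postn and Col14a1 (0.87 ± 0.34) among its members. It was -0.33 for fatty acid uptake and oxidation (adjusted p = 1.3e-04), 0.33 for fibroblasts (0.0236) and 0.38 for aryl hydrocarbon and xenobiotic response (0.0236), where Gsta3 (2 ± 0.81) and Tiparp (0.81 ± 0.34) had the smallest p. It was 1.19 for mesothelium and epicardium (0.00803) and -1.16 for microRNA genes of muscle and heart (0.00803). All of these 6 calls were lost, with adjusted p = 0.51 with an estimated correlation. Without 1 library the fibroblast, xenobiotic, mesothelial and microRNA calls were lost in 7, 7, 6 and 4 fits, up to adjusted p = 0.169 and 0.356 without filtered-air sham replicate 2 for fibroblasts and mesothelium, 0.291 without diesel sham replicate 1 for the xenobiotic list and 0.124 without filtered-air sham replicate 3 for microRNA genes.

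The first pattern weighed is the larger number of genes called for TAC after diesel exhaust, 442 against 113 over all genes. Depth as the whole cause is argued against, since with all libraries thinned to the smallest total in 5 draws the ratio of the calls had a median of 3.76 and a range of 3.47 to 3.89. A lower share of cardiomyocytes in the diesel TAC hearts as the whole cause is argued against only weakly, since it would raise markers of all other cell types alike. Against filtered-air TAC hearts the median log2 difference was 0.0153 for endothelium, 0.0528 for smooth muscle and pericytes, 0.132 for macrophages and 0.232 for fibroblasts. Fibroblasts exceeded endothelium by 0.217 (bootstrap interval over markers 0.0146 to 0.376), and per heart this difference rose by 0.317 ± 0.117. The groups did not overlap but nearly touched, at 0.0244 in filtered-air TAC replicate 2 and 0.0291 in diesel TAC replicate 1. The fibroblast list also holds matrix genes that rose after TAC, such as Col1a1 and Lum. A change in the fibroblasts stays open. Chance assignment of hearts to exposure could not be excluded, since the difference of 329 calls was reached in 38 of 100 groupings, with 1120 at most in another grouping, and the difference of median size of 0.172 in 23 of 100, with 0.304 at most. Of the 29 groupings with 1 first-listed library in each group, as in the real one, 11 and 6 reached them. The prenatal exposure, which the design names, stays open beside it. No gene passed the interaction by edgeR with the expression filter, and these groupings do not set exposure apart from chance.

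The second pattern is Ptprf and Pamr1, which had the smallest p for the interaction in edgeR with the expression filter. With no filter they had ranks 2 and 3. Pamr1 had rank 7 by voom and rank 9 without the first-listed libraries, with unadjusted p = 0.0017 and 0.00134, so that its rank depends on the setting. Without 1 library their ranks also moved, with Ptprf at rank 3 without filtered-air TAC replicate 2 and both at ranks 2 and 4 without diesel TAC replicate 1. A single library as the cause of their small p is argued against, since the highest unadjusted p of either gene in the 12 fits without 1 library was 0.000624. Chance could not be excluded: the smallest interaction p, 2.47e-05, was matched in 17 of 100 groupings, with 1.33e-09 at the least in another. Of the 29 groupings with 1 first-listed library in each group 2 reached this p, the real one among them (6.9%), with 6.29e-06 in the other, against 15 of the 71 other groupings. A biological difference between exposures remains possible for both genes on these values.

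Other groupings of the libraries were counted for each result. For TAC averaged over exposure 1 of 100 groupings, the real one, gave as many as 1091 genes, with 32 at most in another. This argues against chance, although 1 of 100 is the smallest share that these groupings can give. For TAC in filtered air (113 genes) and after diesel exhaust (442) the highest other of 10 splits gave 1 gene in each, and for diesel exhaust in sham and in TAC the real and the highest other count were 0 in all 10, with too few splits for a share under 0.05. For the interaction and for diesel exhaust averaged over surgery the real count was 0, which all 100 groupings reach whatever the data, so that this says nothing about chance. The most in another grouping was 38 and 118 genes, which points to a structure of the samples, and 0 and 1 among the 29 with 1 first-listed library in each group. List counts with a preset correlation were common in other groupings too: 7 of 100 reached the 17 lists of averaged TAC (18 at most), 36 of 100 the 6 of the interaction (16 at most) and 53 of 100 the 4 of averaged diesel exhaust (16 at most), so that chance is not excluded. With 10 splits, too few for a share under 0.05, the real and highest other list counts were 15 and 19 for TAC in filtered air, 16 and 16 after diesel exhaust, 1 and 8 for diesel exhaust in sham, and 6 and 14 in TAC. A list count as large as the real one came in 2, 2, 7 and 4 of these splits.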

How the results depend on the processing

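A covariate for a split of the libraries and a fit of the 8 libraries outside it were chosen only after the result was seen. No paired analysis was possible because the labels carry no number that pairs hearts. Of 168 named gene results past the threshold, 164 stayed past it by DESeq2, 160 by voom, 166 with no filter, 168 each with RLE factors, 1 surrogate variable, the split covariate and without mitochondrial and structural RNA, and 136 in the 8 libraries, and no result changed direction. In the fit of the compared groups alone 78 stayed past it and 12 did not, and 73 of the 113 calls for TAC in filtered air were kept. For TAC in filtered air the count was 258 by DESeq2, 247 with no filter, 188 by voom, 192 with the surrogate variable and 261 with the split covariate. For TAC after diesel exhaust it was 676 by DESeq2, 795 by voom, 788 with the surrogate variable and 780 with the split covariate. The balance of rises and falls moved too. In filtered air 83 and 30 became 107 and 81 by voom, 159 and 102 with the split covariate and 34 and 5 without TAC replicate 2. After diesel exhaust 239 and 203 became 376 and 419 by voom and 132 and 56 without TAC replicate 3. The count was 1 for diesel exhaust in sham with the split covariate, 1 for diesel exhaust in TAC by DESeq2 and with no filter, and 1 for the interaction by DESeq2 and with no filter. The 8 libraries gave 132 genes for TAC in filtered air and 365 after diesel exhaust. With an estimated correlation the lists past the threshold numbered 3, 6 and 6 for TAC in filtered air, after diesel exhaust and averaged, and 0 for both exposure comparisons, their average and the interaction. By fry they numbered 8 for TAC in filtered air, 11 after diesel exhaust, with interferon, imprinted, ion channel, endothelial and ventricular lists among these, 15 averaged and 0 for both exposure comparisons, their average and the interaction. In the 8 libraries 10 lists passed for TAC after diesel exhaust, 3 for diesel exhaust in sham and 7 for its average over surgery. For diesel exhaust in sham 2 passed with the split covariate, and 0 without mitochondrial and structural RNA, which takes out the only list that had passed and so shows nothing. The correlation of both TAC responses was 0.154 with no filter and 0.673 with at least 5 CPM, against 0.524. Leaving out each library in turn gave 39 to 143 genes for TAC in filtered air, 188 to 530 after diesel exhaust, 631 to 1213 averaged, and 0 to 0 for diesel exhaust in sham, in TAC and averaged and for the interaction. In the same order of comparisons the lists numbered 11 to 18, 11 to 17, 15 to 18, 0 to 3, 4 to 10, 3 to 6 and 3 to 15, and the correlation ran from 0.322 to 0.526. The cause was not tested, except that the strict filter tests fewer genes and the 8 libraries hold fewer samples. Depth limits genes near the floor of 0.226 to 0.542 CPM per library.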

Other observations

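The tests of small RNAs, transcript length, lower depth and higher depth were chosen only after the result was seen, while that of another cell type was set before.

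Several lists did not pass by camera in any comparison, and their values for TAC are given as mean log2 changes in filtered air and after diesel exhaust. They were 0.31 and 0.32 for 28 oxidative stress genes, 0.01 and 0.04 for 30 genes of the unfolded protein and heat shock response, -0.06 and -0.05 for 36 DNA methylation and chromatin enzymes, 0.00 and 0.17 for 22 imprinted genes and 0.09 and 0.12 for 43 cytosolic ribosomal proteins. By fry the imprinted genes passed for TAC after diesel exhaust (adjusted p = 0.0158) and averaged over exposure (0.0332). In the average of both exposures 3 oxidative stress genes rose and 1 fell, 1 heat shock gene rose and 4 fell, 1 chromatin enzyme rose and 3 fell, 3 imprinted genes rose and 1 fell, and 1 ribosomal protein gene fell. Among cell types, smooth muscle and pericytes had -0.12 and 0.19, erythrocytes 0.03 and 0.39, adipocytes -0.17 and -0.05, atrial cardiomyocytes 0.08 and 0.30, skeletal muscle 0.54 and 0.26, and Schwann cells and neurons -0.14 and -0.23. These means hide members that moved both ways: in the average of both exposures 2 smooth muscle markers rose and 3 fell, 1 adipocyte marker rose and 4 fell, as after diesel exhaust alone, 2 atrial markers rose and 4 fell, 2 skeletal muscle markers rose and 1 fell, and 1 Schwann cell marker rose and 1 fell. The 5 sex-linked genes had -0.61 and 0.20, while over the 12 libraries Xist lay at 0 to 2.92 CPM and Ddx3y at 26.7 to 68.9 CPM, levels of male hearts in each. Too few markers of neutrophils (3), T and B lymphocytes (3), lung (1) and thymus (1) were measured for a test.

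The libraries also differed within groups. The first-listed library of each of the 4 groups departed from its group mean in a common direction, with correlations between their departures of 0.133 to 0.254. They were picked by this common departure, so positive correlations follow in part from the choice. A model with this split as a covariate called 799 genes, 449 higher and 350 lower in the 4 libraries, which is no independent evidence since the split came from the same data. In each group snoRNA and microRNA genes were lower in these libraries, with median log2 differences of -1.21 and -0.50 in filtered-air sham, -1.63 and -1.33 in filtered-air TAC, -1.02 and -0.81 in diesel sham, and -0.53 and -0.80 in diesel TAC. These libraries had the highest total of their group in each of the 4 groups, by 3.83% at the least, so that lower depth is excluded. At equal totals they nonetheless had a count for fewer genes, by 8.32% and 7.2% in filtered-air sham and TAC and 2.89% and 3.05% in diesel sham and TAC, so that a lower complexity of these libraries stays open. After thinning to equal totals the lowest correlation between their departures was 0.119 or more in each of 5 draws, against 0.133 before. This argues against a higher number of counts as the whole cause. The same libraries were kept for this without picking them again, so their first choice still favours a correlation above 0. Thinning changes only the number of counts, so other effects that go with higher depth are not excluded. None of the 9 lists tested for cells other than cardiomyocytes moved in 1 direction in all 4 groups (smallest shared difference 0). In filtered-air sham, filtered-air TAC, diesel sham and diesel TAC, macrophage markers had median differences of -0.465, -0.25, -0.463 and 0.111. Fibroblast markers had -0.0677, -0.275, -0.154 and 0.0498. The sign in diesel TAC rests on 1 library and no spread was computed, so another cell type is not excluded. For transcript length, short minus long genes gave -0.0822, -0.0647 and -0.0593 in filtered-air sham, filtered-air TAC and diesel sham but 0.12 in diesel TAC. Each had a bootstrap interval over genes that leaves out 0, so the 4 groups did not share 1 direction. These intervals do not measure the spread between libraries, and the sign in diesel TAC again rests on 1 library. Transcript length is therefore not excluded. A loss of small RNAs in preparation stays open. In 28 small RNA genes other than snoRNA and microRNA genes the median difference was -0.747, -0.773, -0.312 and 0.41 in these groups, and the intervals for diesel sham (-1.3 to 0.145) and diesel TAC (-0.44 to 0.765) are too wide to decide. The design names no biological difference between these libraries. Each sequencing run held 4 samples, but the sources do not say which. Whether these libraries shared a run could not be tested and stays open.

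Diesel sham replicate 2 had the lowest mitochondrial share, 18.3% of counts, and the highest share taken by 1 gene without a symbol, 7.01%. Over the 12 libraries this gene took 2.36% to 7.01% of counts. It was not among the 239 structural RNA genes, whose nuclear members held 6.22% of counts in diesel sham replicate 2. The fit without mitochondrial and structural RNA therefore kept its counts. Whether it is itself a structural RNA was not tested.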
